A study of Homo sapiens with 9 samples.

How the data were processed

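RNA was measured in 9 libraries of MCF10A MII cells in 3 series (no-siRNA, siControl and siJUNB, the siRNA pools at 25 nM), each untreated, after 1.5 h and after 16 h of TGFβ3 at 5 ng/ml. PolyA RNA was fragmented and made into libraries with dUTP marking of the second strand, per the labels' protocols. The no-siRNA series was sequenced on a HiSeq 2000 and the siRNA series on a HiSeq 2500, per the labels' protocols. The values used were gene-level FPKM made by the authors, with a lower and an upper bound of an interval whose level is not given in the sources used here. TopHat, Cufflinks 2.0.13, Picard and SAMtools and the build hg19 were named per the submitters' processing notes, and their settings, the annotation and the scaling between libraries are not given in the sources used here. Gene coordinates in the text are those of the authors' table on hg19.

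The table held 25268 genes, of which 17 with a status other than OK were left out. Genes with an FPKM of at least 1 in at least 2 of the 9 libraries were tested, 12156 in all, 98 of them small RNA genes. Of the tested genes 3635 share a locus with another gene, and their values are less certain. Sums of FPKM ran from 570315 to 930284 between libraries, the largest being 1.63 times the smallest, and the 10 genes with the highest values took 9.50% to 15.52% of a sum. Small RNA genes took 3.21%, 9.80% and 3.87% of the sum in no-siRNA (untreated, 1.5 h, 16 h), 4.33%, 2.79% and 2.38% in siControl and 4.52%, 6.54% and 2.82% in siJUNB cells. Read numbers cannot be derived from FPKM. The value of a single fragment relative to the untreated library, estimated from ratios of low values as a rough guide to relative depth, was 0.674 to 1.37 times. The authors' interval had a median width of 1.35 to 1.37 times the value, so that the value of a single library is imprecise.

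Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the prior variance and Benjamini-Hochberg adjustment over the tested genes, and genes were called at adjusted p under 0.05. The effect of TGFβ3 at 1.5 h, at 16 h and between these times, and the difference of siControl from no-siRNA, came from an additive fit of series and time to the 6 libraries of the control series. The average effect of JUNB siRNA came from a fit of siRNA with time as a block to the 6 siControl and siJUNB libraries. The error of this fit is how far the siRNA difference varied between the times, so that a difference at 1 time only is not favoured. The difference of the response between siJUNB and the mean of both control series came from a fit with 7 coefficients to all 9 libraries. This fit follows the 3 siJUNB libraries exactly, so its spread came from the control series alone (median residual SD 0.137 in both fits), and the siJUNB libraries are assumed to vary like them. Each fit had 2 residual degrees of freedom. The scripts were tested on simulated data with normal noise at the spread that limma estimated in the control series. There, the 16 h effect of TGFβ3 was recovered for 37.3% of genes changed 1.5-fold and 91.0% of genes changed 2-fold. The average effect of JUNB siRNA was recovered for 62.7% of genes changed 1.5-fold. The spread of the siJUNB libraries did not enter. With the prior variance counted, the fit of JUNB siRNA had 4.64 degrees of freedom, against 7.2 in that of the control series. The share recovered for JUNB siRNA may therefore be too high. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

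The samples, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named JUNB and each AP-1 gene past the filter, and for each tested comparison the 10 largest rises and falls past adjusted p 0.05 with the same sign in both control series (TGFβ3) or at all 3 times (JUNB siRNA). Where fewer than 10 passed, genes changed at least 2-fold in each series or time were added by size and are given as not past the test. Of each list, the 2 to 4 members with the largest absolute change could be named. Genes without a symbol and small RNA genes, taken by the symbols of microRNA, small nuclear, nucleolar and Cajal body, vault and Y RNA genes, were left out of this rule, and some genes it names are not reported here. The lists covered SMAD feedback targets, AP-1, TGFβ ligands and receptors, mesenchymal and epithelial markers, proteases, matrix, integrins, WNT, Notch, ID and cytostatic genes, cell cycle, interferon, cholesterol, NF-kB, ERK, YAP/TEAD, p53, unfolded protein response, glycolysis, basal, keratinocyte differentiation and luminal genes, stromal markers, housekeeping and ribosomal protein genes. For each the median change was set beside 10000 random lists matched on expression in 20 bins, as description only. Panels of genes changed at least 2-fold in the no-siRNA series were measured in the other series, without a test.

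Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, an FPKM of at least 5, median-ratio and upper-quartile rescaling (factors under 0.1 on the log2 scale), limma without the trend, all 3 series as blocks, leaving out each time, siJUNB against no-siRNA, siJUNB against the siControl response alone and panels at 1.5-fold and 3-fold. Chosen after the data were seen were the tests without small RNA genes, the panel of lowered genes, rescaling of the JUNB level, and removal of a smooth function of transcript length and GC content from each library, with a fit of the same genes without removal beside it. Length and GC came from transcripts of GENCODE v29 matched by gene symbol for 11430 genes (94.0% of those tested), with the median over transcripts linked to RefSeq. This definition replaced the longest transcript after the first outcome had been seen, and both outcomes are given in the closing section.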

Results

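Transcript levels were measured in MCF10A MII cells, an H-Ras-transformed derivative of the human breast epithelial line MCF10A, by sequencing of strand-marked cDNA libraries from polyA RNA. The 9 libraries formed 3 series. The first series carried no named siRNA (no-siRNA), the second received a control siRNA pool at 25 nM (siControl) and the third a pool against JUNB at 25 nM (siJUNB). Each series held an untreated library, a library after 1.5 h and a library after 16 h of recombinant TGFβ3 at 5 ng/ml, so that each of the 9 groups had 1 library and no replicate. The study concerned the AP-1 subunit JUNB as a partner of the SMAD transcription factors in the response to TGFβ. Values were FPKM, fragment counts scaled by transcript length and library size, on hg19 gene models, and fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Between 11305 and 11509 genes reached an FPKM of 1 in a library, and the median FPKM of the 12156 tested genes lay between 8.90 and 9.21. The number of reads per library is unknown. Small RNA genes took 9.80% of the FPKM sum in the no-siRNA library after 1.5 h, 6.54% in the siJUNB library after 1.5 h and 2.38% to 4.52% in the other libraries. P-values measure only the spread between these libraries, which may be technical.

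JUNB, the gene targeted by the siRNA pool, was lower in the siJUNB library than in the siControl library at each time. The gene lies on chromosome 19 at 12902310 to 12904125. Its FPKM in siJUNB cells was 22.7 untreated, 85.2 after 1.5 h and 111 after 16 h of TGFβ3, against 65.01, 183 and 257 in siControl cells, which left 34.95%, 46.51% and 43.38% of the siControl level. In the no-siRNA series it was 39.7, 190.0 and 173 FPKM, so that the siJUNB level was 57.2%, 44.9% and 64.5% of that series. The authors' intervals of the untreated libraries, 8.76 to 36.7 FPKM for siJUNB and 26.7 to 103 FPKM for siControl, overlapped. Averaged over the 3 times, JUNB fell by 1.26 with the JUNB siRNA (SE 0.094, limma adjusted p = 0.036). It was lower in every setting but did not pass in 5 of them, with limma adjusted p of 0.0725 without the variance trend, 0.165 without the filter on low values, and 0.148, 0.197 and 0.0578 without the untreated, the 1.5 h and the 16 h pair. TGFβ3 raised JUNB in each series, 4.78-fold after 1.5 h and 4.35-fold after 16 h in no-siRNA cells, 2.82-fold and 3.95-fold in siControl cells, and 3.75-fold and 4.90-fold in siJUNB cells.

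Of the 14 measured AP-1 family genes, which encode subunits and relatives of the AP-1 transcription factor, 3 rose in the control series after 1.5 h and 7 rose and 2 fell after 16 h. Adjusted over the list alone, 6 rose after 1.5 h, and 7 rose and 2 fell after 16 h. JUN rose by 2.12 after 1.5 h (SE 0.27, limma adjusted p = 0.0277) and by 1.95 after 16 h (SE 0.27, limma adjusted p = 0.00146). FOSB rose by 1.54 after 1.5 h, and FOS by 2.08 after 16 h (SE 0.23, limma adjusted p = 0.00061). FOSL2, MAFF and MAFG rose by 0.66, 0.68 and 0.47 after 16 h, and FOSB was still 0.75 above the untreated level. ATF3 and BATF3 fell by 0.84 and by 0.97 after 16 h, from untreated values of 1.69 to 4.18 FPKM. The 16 h changes of FOSL1 (-0.58), ATF2 (0.47), JDP2 (0.17), MAFK (0.096) and JUND (-0.083) did not pass the test. With JUNB siRNA, JUNB was the 1 member that passed over all genes, and adjusted over the list alone 3 members fell and 1 rose. FOSL1 differed by -0.53 (SE 0.082, limma adjusted p = 0.06), FOS by -0.58, JUN by -0.45 and JDP2 by 0.52, none of them past the test over all genes.

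**Figure D1:**
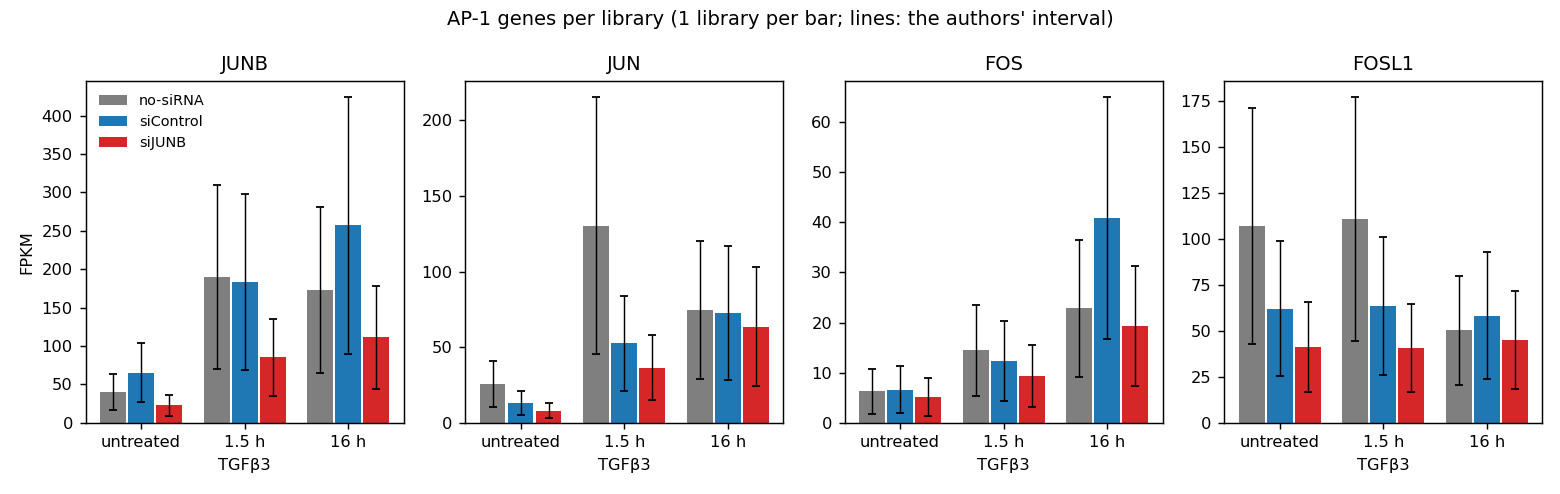
FPKM of JUNB, JUN, FOS and FOSL1 in each library (1 library per bar), by time of TGFβ3 and series, with lines for the authors' interval of each value. JUNB in the siJUNB bars reaches 22.7, 85.2 and 111 FPKM against 65.01, 183 and 257 in the siControl bars.

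The early response was taken as the mean change after 1.5 h of TGFβ3 over the no-siRNA and siControl series. Of the 45 genes that rose, 8 belong to the list of SMAD feedback and immediate target genes. ID3, an inhibitor of differentiation that lacks a DNA-binding region, rose by 3.15 (SE 0.17, limma adjusted p = 0.000787), from 22.6 to 241 FPKM in no-siRNA and from 63.6 to 496 FPKM in siControl cells. Its relatives ID2 and ID1 rose by 2.95 and 2.001. The matricellular growth factor gene CTGF rose by 3.05 (SE 0.17), the inhibitory SMAD gene SMAD7 by 2.37 (SE 0.13) and the SMAD co-repressor gene SKIL by 2.07 (SE 0.18). FOXC2, a forkhead transcription factor of mesenchymal cells, rose by 2.54, the focal adhesion scaffold gene NEDD9 by 2.31 and the transcriptional cofactor gene LBH by 2.19.

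After 1.5 h, 45 of the 12156 genes rose and 5 fell, and at unadjusted p under 0.05 the numbers were 498 and 153. The 5 that fell were CITED2, a transcriptional coactivator partner (-1.42, SE 0.14), FAM46A (-1.34, SE 0.19), CEBPD, an inflammatory transcription factor (-1.34, SE 0.16), the chemokine gene CXCL3 (-1.15, SE 0.15) and MYC, a driver of cell growth (-0.98, SE 0.12), with limma adjusted p from 0.0127 to 0.0463. SPRY1, an inhibitor of receptor tyrosine kinase signalling (-1.39), CXCL2 (-1.18) and the pseudogene HNRNPA1P10 (-2.05) were at least 2-fold lower in both series and did not pass. Of the 21 measured SMAD feedback and immediate target genes, 8 rose, and 17 adjusted over the list alone. Among 13 ID and cytostatic genes 3 rose and 1, MYC, fell (4 and 1 adjusted over the list alone). Of 16 mesenchymal markers and regulators of epithelial-mesenchymal transition, FOXC2 and SNAI1 (1.66, SE 0.16) rose, and of 22 proteases and protease regulators 2 rose, among them the urokinase gene PLAU (1.86, SE 0.13), each list with 3 adjusted over the list alone. The ligand gene WNT9A (1.62) rose in the WNT list, JAG1 (1.28) in the Notch list, the epithelial transcription factor gene OVOL1 (1.42) among epithelial markers, and CTGF and CYR61 (0.92) among YAP/TEAD targets. Adjusted over the list alone, 2 WNT genes rose and 2 fell, and the counts of the Notch, epithelial and YAP/TEAD lists stayed at 1, 1 and 2 rises. The 22 NF-kB and inflammatory genes had a median of -0.21, with CXCL3 the 1 fall over all genes and 5 falls adjusted over the list alone. None of 25 matrix genes, 11 integrins or 28 cell cycle genes passed the test over all genes, and adjusted over the list alone 3 matrix genes and 1 integrin rose. The early changes went with the GC content of the transcripts (Spearman's rho 0.42 across 11430 genes, which are not independent replicates), and over these genes the calls numbered 48 and 4 before and 19 and 4 after removal of length and GC trends. Without the filter on low values 0 genes were called in either direction, against 534 and 327 at unadjusted p under 0.05 (limma).

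After 16 h of TGFβ3 the same series showed a much wider response, with 2518 genes higher and 2441 lower, of which 788 and 819 changed at least 2-fold. The largest rises included those of secreted protease and matrix genes. MMP10, stromelysin 2, rose by 6.94 (SE 0.44, limma adjusted p = 6.81e-05), from 6.30 to 417 FPKM in no-siRNA and from 1.14 to 564 FPKM in siControl cells. FN1, fibronectin, rose by 6.29 (SE 0.20), from 3.74 to 283 and from 2.96 to 402 FPKM and MMP1, interstitial collagenase, by 5.87 (SE 0.23). The cytokine gene IL11 rose by 4.47, the gelatinase gene MMP9 by 4.47, the secretory granule gene SCG5 by 3.97, C4orf26 by 3.96, PLAU by 3.93 and the transglutaminase gene TGM2 by 3.89. FN1 lies on chromosome 2 at 216225179 to 216300791, and MMP10 on chromosome 11 at 102641233 to 102651359. MMP1 lies beside it on chromosome 11 in a locus shared by 3 genes.

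The 16 h falls were led by genes of DNA replication and mitosis. All 28 measured S and G2/M genes fell, with a median of -2.61, among them the topoisomerase gene TOP2A (-3.36, SE 0.13), the ribonucleotide reductase subunit RRM2 (-3.30, SE 0.12), the mitotic kinesin KIF20A (-3.27) and the mitotic kinase PLK1 (-3.03). FAM111B (-3.55, SE 0.15), CDCA3 (-3.47), CDCA5 (-3.32), the lamin gene LMNB1 (-3.30) and the replication genes CDC45 (-3.21) and GINS2 (-3.20) fell as well. PTGES, the inducible prostaglandin E synthase, fell by 3.35. All of these falls had limma adjusted p under that of CDCA3, which was 7.76e-05. In the ID and cytostatic list 4 genes rose and 4 fell (5 and 4 adjusted over the list alone), with falls of E2F1 (-2.89), CDC25A (-2.27), MYC (-1.46) and CDKN2C (-1.37).

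Of 22 measured proteases and protease regulators 19 rose and 0 fell, of 16 mesenchymal genes 13 rose and 0 fell, of 11 integrins 10 rose and 0 fell, and of 25 basement membrane and matrix genes 21 rose and 1 fell. These counts did not change when adjusted over the list alone. Besides FN1, the mesenchymal rises were led by FOXC2 (2.42), the smooth muscle gene TAGLN (2.16) and tropomyosin 1, TPM1 (2.13). The matrix rises included the laminin chain gene LAMA3 (3.29) and TGFBI (2.80), and the integrin rises ITGA2 (3.09), ITGB6 (2.51), ITGB4 (2.04) and ITGA5 (1.71). Of the SMAD feedback list 18 rose and 1 fell, among them IL11, TGFBI and PDGFB (2.52). Of 25 TGFβ ligands, receptors and modulators 14 rose and 2 fell (15 and 3 adjusted over the list alone), led by BMP2 (3.84), FSTL3 (2.88), TGFB1 (2.17) and LTBP2 (2.14). Of 15 WNT genes 9 rose and 3 fell, with WNT9A (2.48), WNT7A (2.31) and WNT7B (1.96) highest. Of 15 basal keratinocyte-type genes 13 rose and 1 fell, led by ITGB4 and the keratins KRT14, KRT17 (1.65) and KRT6A (1.56). Of 27 epithelial markers 7 rose and 6 fell (8 and 7 adjusted over the list alone), and their changes went both ways: the epithelial transcription factor gene ELF3 fell by 2.79 and the tight junction gene TJP3 by 1.32, while the desmosomal genes DSP (1.27) and DSC2 (1.07) rose.

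Among the remaining lists at 16 h, 11 of 18 unfolded protein and ATF4 response genes rose and 3 fell, with HERPUD1 (1.85), a component of protein degradation at the endoplasmic reticulum, and the co-chaperone gene DNAJB9 (1.48) higher and the serine synthesis gene PSAT1 (-1.80) lower. NF-kB and inflammatory genes had 10 rises and 3 falls, with CSF2 (1.97), IL6 (1.79) and PTGS2 (1.23) highest, 11 and 3 adjusted over the list alone. ERK and RAS targets had 10 rises and 2 falls, with IER3 at 1.32, DUSP6 at 1.25 and MYC at -1.46. Notch genes had 3 rises and 1 fall, with JAG1 at 2.31 and NRARP at -1.26, YAP/TEAD targets 5 and 2 (7 and 2 adjusted over the list alone), with NT5E at 1.78 and CTGF at 1.42, and p53 targets 3 and 5, with TP53I3 at 1.73 and PLK2 at -1.60. Keratinocyte differentiation genes had 6 and 3, with LCE3D at 3.69 and KLK10 at -1.95, luminal markers 3 and 1 (3 and 2 adjusted over the list alone), with FOXA1 at -1.27 and SPDEF at 1.13, and interferon-stimulated genes 3 and 4, with IRF9 at 1.37 and STAT2 at 1.13. Cholesterol synthesis genes had 2 rises and 6 falls (1 and 4 adjusted over the list alone), with HMGCS1 at -0.60 and MVK at -0.53, and glycolysis and hypoxia genes 2 and 1 (1 and 1 adjusted over the list alone), with NDRG1 at 1.68 and HK2 at -1.40. Of 15 housekeeping genes 1 rose, ACTB (1.18), and 3 fell, among them HPRT1 (-1.11) and TUBB (-0.66). Of the 37 ribosomal protein genes 0 passed the limma test in either direction, the largest change being that of RPS14 (0.32). Of 20 markers of immune, endothelial and stromal cells 3 were measured, and of these CD68 rose by 1.203 and CD14 fell by 2.21. Mitochondrially encoded genes were not analysed here.

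Across 12058 genes other than small RNA genes, the 16 h response of the siControl series correlated with that of the no-siRNA series with Pearson's r = 0.844 and Spearman's rho = 0.795, and at 1.5 h with r = 0.269 and rho = 0.075. These are correlations across genes, which are not independent replicates. Without the filter on low values the 16 h calls numbered 1270 and 1225.

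**Figure D2:**
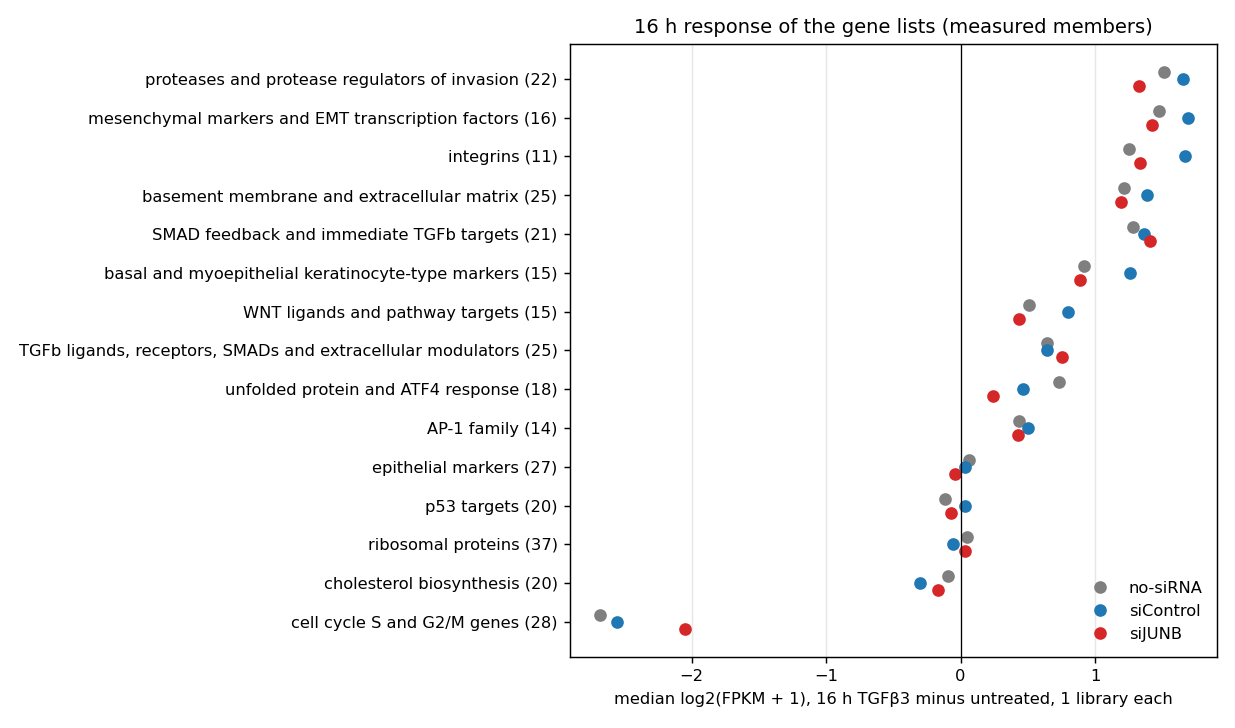
Median 16 h response, log2(FPKM + 1), of the measured members of 15 gene lists (number in brackets), 1 point per series. The cell cycle list lies at -2.68 in no-siRNA, -2.55 in siControl and -2.05 in siJUNB cells, and the protease list at 1.51, 1.66 and 1.32.

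Between 1.5 h and 16 h, 2168 genes rose and 2338 fell in the control series. MMP10 (6.02, SE 0.44), FN1 (5.802, SE 0.20) and MMP1 (5.30, SE 0.23) rose mainly in this interval, with limma adjusted p of at most 0.000159, as did MMP9 (4.42), the collagenase gene MMP13 (3.71), LCE3D (3.47), TGM2 (3.44), BMP2 (3.33), the tubulin gene TUBA1A (3.28) and C4orf26 (3.27). The early ID genes went the other way, with ID2 lower by -2.66 and ID3 by -2.04 at 16 h than at 1.5 h. CTGF fell by 1.63, ATF3 by 1.68 and SMAD6 by 1.71 in the same interval. The cell cycle genes fell in this interval too (28 of 28, median -2.55), and the largest falls of all genes were those of CDCA3 (-3.40), PTGES (-3.29), FAM111B (-3.27), LMNB1 (-3.15), RRM2 (-3.10), the kinetochore gene SPC24 (-3.10), CDCA5 (-3.10), KIF20A (-3.09), TOP2A (-3.09) and the histone chaperone gene ASF1B (-3.07). Of the NF-kB and inflammatory list 11 rose and 0 fell between the times, including CXCL3 (1.58), which had fallen at 1.5 h. Without the filter on low values 831 and 965 genes were called.

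The effect of JUNB siRNA was taken as the mean difference between the siJUNB and siControl libraries over the 3 times, which share an instrument. SMIM3, a small membrane protein gene, fell by 2.07 (SE 0.088, limma adjusted p = 0.0209), and its FPKM was 5.95, 5.91 and 11.3 against 27.4, 31.0 and 46.9. INHBA, the activin A subunit of the TGFβ family, fell by 1.71 (SE 0.16, limma adjusted p = 0.0447), from 10.6 to 1.80 FPKM in untreated cells. The calcium-binding protein gene CALB2 fell by 1.54 (SE 0.070), the parathyroid hormone-related gene PTHLH by 1.51 (SE 0.12), the lipid transfer protein gene PCTP by 1.46 and HBEGF, an EGF receptor ligand, by 1.39. GABRP, a subunit of the GABA-A receptor, rose by 2.07 (SE 0.13, limma adjusted p = 0.0296), from 1.80 to 8.76 FPKM in untreated cells, and FOXI1, a forkhead transcription factor, by 1.85 (SE 0.25). In untreated siControl cells several of these genes already differed from no-siRNA cells in the same direction. The untreated no-siRNA FPKM was 47.9 for INHBA, 125 for CALB2, 106 for PTHLH, 44.6 for HBEGF, 0.104 for GABRP and 0.68 for FOXI1. It was 15.1 for PCTP, near the siControl value of 15.0, and 12.5 for SMIM3, below siControl. Whether the differences are particular to the JUNB pool was not tested.

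In total 50 genes rose and 209 fell with JUNB siRNA, and 1033 and 1919 had an unadjusted p under 0.05 in limma. The differences went weakly with transcript length (Spearman's rho 0.209) and GC content (-0.137) across 11430 genes, which are not independent replicates. Other large rises were those of GRAMD2 (1.66), RARRES1, a retinoic acid-induced gene (1.60), the neurotrophin receptor gene NGFR (1.43), LOXL4, a lysyl oxidase relative (1.34), PADI2, a protein citrullinating enzyme (1.28), CYP1B1, a cytochrome P450 (1.26) and the histone gene HIST1H2BF (1.21). C10orf10 fell by 1.40 and ZBED2 by 1.39. The antisense gene ITGB2-AS1 (1.41), the pseudogene RPSAP52 (-2.09) and the decoy receptor gene TNFRSF6B (-1.69) passed too, but share their loci with other genes, so that their values are uncertain. NGFR, INHBA, C10orf10, ZBED2 and PLAU also lie in loci shared by 2 or 3 genes. The counts rested on few libraries and on the settings: 5 rose and 27 fell with a pseudocount of 0.1, 9 and 35 with median-ratio rescaling, 14 and 28 with upper-quartile rescaling, 0 and 0 in limma without the variance trend (1141 and 1748 at unadjusted p under 0.05), and at most 2 and 17 when 1 time was left out. The 20 genes with the largest changes kept their direction under every setting in which they were tested (CYP1B1 and HIST1H2BF did not enter that with an FPKM of at least 5, nor GRAMD2 and C10orf10 those limited to genes with length and GC values), and all 20 lost the call without the trend, without the filter, without the untreated pair and without the 1.5 h pair.

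The protease list had the lowest median with JUNB siRNA, -0.64 over 22 genes, below those of 10000 expression-matched random lists (95% of them from -0.19 to 0.027). In it 6 genes fell and 0 rose (11 and 2 adjusted over the list alone), with ADAM19 (-1.08, SE 0.12) and PLAU (-1.05, SE 0.12) past the test at limma adjusted p = 0.0482. The larger differences of MMP1 (-2.31, SE 0.52) and MMP10 (-1.74, SE 0.50) did not pass, at limma adjusted p of 0.0961 and 0.132. The error of this test is how far the difference varied between the 3 times. A difference that changes with TGFβ3 is therefore less likely to pass. The list median was -0.33 in untreated cells, -0.40 after 1.5 h and -0.92 after 16 h. Of the basal keratinocyte-type genes 6 fell and 0 rose (10 and 0 adjusted over the list alone), with KRT6A at -1.15, the calcium-binding protein gene S100A2 at -0.92 and the 14-3-3 gene SFN at -0.85, and a median of -0.46. Of the glycolysis and hypoxia genes 4 fell and 0 rose (8 and 0 adjusted over the list alone), with the stress-response gene NDRG1 at -1.31, the carbonic anhydrase gene CA9 at -1.29 and lactate dehydrogenase LDHA at -0.65. Their median of -0.44 came from -0.56 in untreated cells, -0.51 after 1.5 h and -0.21 after 16 h, the last inside the range of random lists (-0.26 to 0.11). Of the NF-kB and inflammatory genes CXCL8 (-1.36), CSF2 (-1.06) and 1 other fell (6 down and 1 up adjusted over the list alone).

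Smaller counts were found in the other lists with JUNB siRNA. Of the integrins ITGA5 (-0.86) and ITGA3 (-0.60) fell, of the ERK targets HBEGF and IER3 (-0.64), of the unfolded protein list TRIB3 (-1.01) and SDF2L1 (-0.72), and of the housekeeping genes ACTB (-0.50) and GAPDH (-0.35). FZD8 (-0.96) fell in the WNT list, JAG1 (-0.85) in the Notch list, SPRR1A (-1.03) among keratinocyte differentiation genes, MUC1 (-0.53) among luminal markers and RPS15 (-0.41) among ribosomal protein genes. SPARC (0.65) rose in the mesenchymal list, TJP3 (1.00) among epithelial markers, LOXL4 among matrix genes and PLK2 (1.11) among p53 targets, of which 6 rose adjusted over the list alone. Of the ligands and receptors 1 rose and INHBA fell. Rises and falls adjusted over the list alone numbered 1 and 3 for integrins, 1 and 6 for ERK targets, 0 and 5 for the unfolded protein list, 0 and 6 for housekeeping genes, 1 and 2 for WNT, 1 and 1 for Notch, 0 and 4 for keratinocyte differentiation, 0 and 2 for luminal markers and 0 and 1 for ribosomal protein genes. They were 1 and 2 for mesenchymal genes, 5 and 3 for epithelial markers, 4 and 6 for matrix genes and 1 and 4 for ligands and receptors. The 20 cholesterol synthesis genes had a median of -0.34 with 0 calls over all genes and 15 falls adjusted over the list alone, MSMO1 being the largest at -0.55. SMAD feedback, ID and cytostatic, cell cycle, interferon-stimulated, YAP/TEAD and stromal lists had 0 calls in either direction in limma over all genes.

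**Figure D3:**
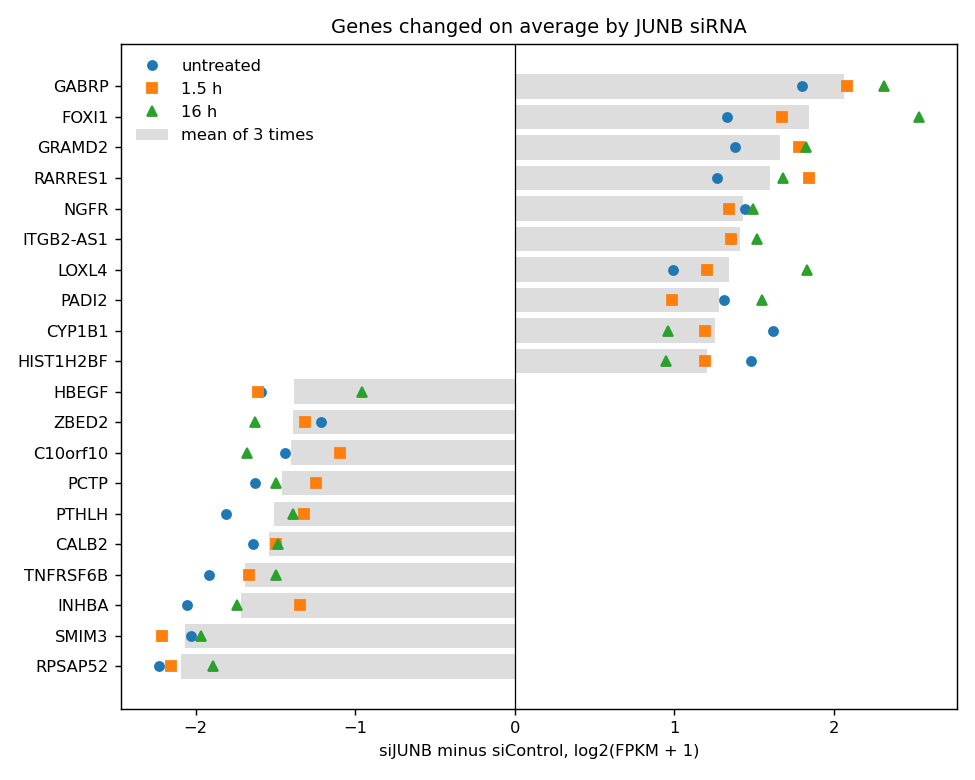
Difference between the siJUNB and siControl libraries, log2(FPKM + 1), at each of the 3 times (points) and their mean (bars) for the 10 largest rises and 10 largest falls past the test. GABRP lies between 1.80 and 2.31 and SMIM3 between -2.21 and -1.97 over the times.

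Whether JUNB siRNA altered the response to TGFβ3 itself was asked of each gene as the response in siJUNB cells minus the mean response of both control series. Each siJUNB response rests on 1 library per time, and the spread in this test is that of the control series, which the siJUNB libraries are assumed to share. At 1.5 h 4 genes were called higher and 0 lower, at 16 h 2 higher and 0 lower, all of them small nucleolar or Cajal body RNA genes whose values reached 0 in some libraries. At unadjusted p under 0.05 in limma, 42 genes were higher and 89 lower at 1.5 h, and 650 and 473 at 16 h. No protein-coding gene passed. The 1.5 h differences went with GC content (Spearman's rho -0.458) and transcript length (0.19) across 11430 genes, which are not independent replicates. At 16 h these were -0.151 and 0.007. In simulated data with normal noise at the spread of the control series, the test recovered 16.4% of 2-fold and 92.4% of 4-fold differences of the 16 h response.

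By size, and small RNA genes aside, the largest difference in the 16 h response among the genes that differed at least 2-fold from both control series was that of the antisense RNA gene CELSR3-AS1 (-3.61), which did not pass (limma adjusted p = 0.222). It came from the untreated siJUNB library alone (11.2 FPKM), since CELSR3-AS1 was at 0 FPKM in both control series untreated and in all series at 16 h. DKK1, a secreted WNT inhibitor (chromosome 10, 54074041 to 54077417), differed by 2.31 (SE 0.25, limma adjusted p = 0.103). Its FPKM went from 133 to 59.5 in no-siRNA and from 57.1 to 24.7 in siControl cells, and from 41.8 to 93.6 in siJUNB cells. FERMT1, the kindlin-1 gene of integrin activation (chromosome 20, 6055492 to 6104191), differed by -2.47 (SE 0.27, limma adjusted p = 0.103), with 200.5, 83.1 and 17.0 FPKM at 16 h in the 3 series. DKK1 and FERMT1 passed the test when genes had to reach an FPKM of 5 and when small RNA genes were left out. The differences were -3.20 for MMP9, -2.11 for SCG5, -2.78 for the cornified envelope gene LCE3D, -1.99 for LCE3E, -2.05 for the cytokine signalling inhibitor gene SOCS1 and -2.73 for the scaffold gene AKAP12. That of AKAP12 was -4.01 from the no-siRNA and -1.45 from the siControl response. The control series themselves differed for AKAP12, at 103.8 and 4.91 FPKM after 16 h. Genes near 0 FPKM depend on the pseudocount. With one of 0.1 the differences were -1.73 for LCE3D, -3.97 for LCE3E, -2.78 for SOCS1 and 3.41 for FAM111B. With one of 5 they were -1.83 for LCE3D, -0.81 for LCE3E, -1.04 for SOCS1 and 0.99 for FAM111B. LCE3E was at 0 FPKM in each siJUNB library. That of MMP1, -2.23, rested on the pseudocount and was -0.22 with a pseudocount of 0.1, as MMP1 was already lower in siJUNB than in siControl cells before TGFβ3 (0.082 against 1.35 FPKM) and after 1.5 h (0.166 against 3.75 FPKM). The differences were 2.55 for the Notch feedback gene NRARP, 1.92 for the elastase inhibitor gene PI3, 1.92 for ERVMER34-1, 2.03 for FAM111B and 1.90 for CDCA5. At 1.5 h the 4 lowest differences chosen in the same way were those of the RNA components of RNase P and RNase MRP, RPPH1 (-4.16) and RMRP (-3.99), short RNA genes that the rule by symbol did not leave out, of CELSR3-AS1 (-2.83) and of the interferon-induced gene IFI27 (-2.55), and the highest that of the endothelin gene EDN2 (1.85, and 0.42 with a pseudocount of 0.1), at limma adjusted p of 0.631 or more.

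Several TGFβ3 targets reached a lower level in siJUNB than in both control series at 16 h, without passing the test of the difference. FN1 was at 90.6 FPKM against 283 in no-siRNA and 402 in siControl cells (difference of the response -1.60, SE 0.35, limma adjusted p = 0.312), MMP10 at 79.2 against 417 and 564, and PLAU at 480.3 against 1088 and 1159.8 FPKM. These genes were lower in siJUNB cells before TGFβ3 as well. Untreated MMP10 was at 0.735 FPKM against 6.30 and 1.14, PLAU at 46.8 against 67.7 and 78.6, and FN1 at 2.54 against 3.74 and 2.96. A lower level at 16 h does not by itself show a smaller response. The list medians of the difference at 16 h were -0.29 for proteases (0 calls over all genes, 4 falls adjusted over the list alone), -0.31 for matrix genes, with FN1 and LOXL4 (1.16) furthest from 0 (0 adjusted over the list alone), and -0.40 for integrins, where ITGB6 (-0.88) and ITGA2 (-0.83) fell adjusted over the list alone. The SMAD feedback list had a median of -0.22, with IL11 at -1.82 and CTGF at 0.94 and 3 falls adjusted over the list alone, yet its median response was 1.37 in siControl and 1.41 in siJUNB cells. The interferon-stimulated genes had -0.68, with IFI27 at -1.65 and IRF9 at -1.37, and the glycolysis list 0.47, with PDK1 at 1.28 and HK2 at 1.18, with 0 calls each adjusted over the list alone. The cell cycle list had 0.60, and 11 of its 28 members were higher adjusted over the list alone, led by the replication genes MCM2 (1.35), MCM6 (1.31) and TYMS (1.30). IFI27 went opposite ways in the control series, from 0.523 to 3.24 FPKM in no-siRNA and 7.155 to 5.39 in siControl cells. In siJUNB cells it went from 17.5 to 7.71 FPKM, which is above both control series at 16 h.

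**Figure D4:**
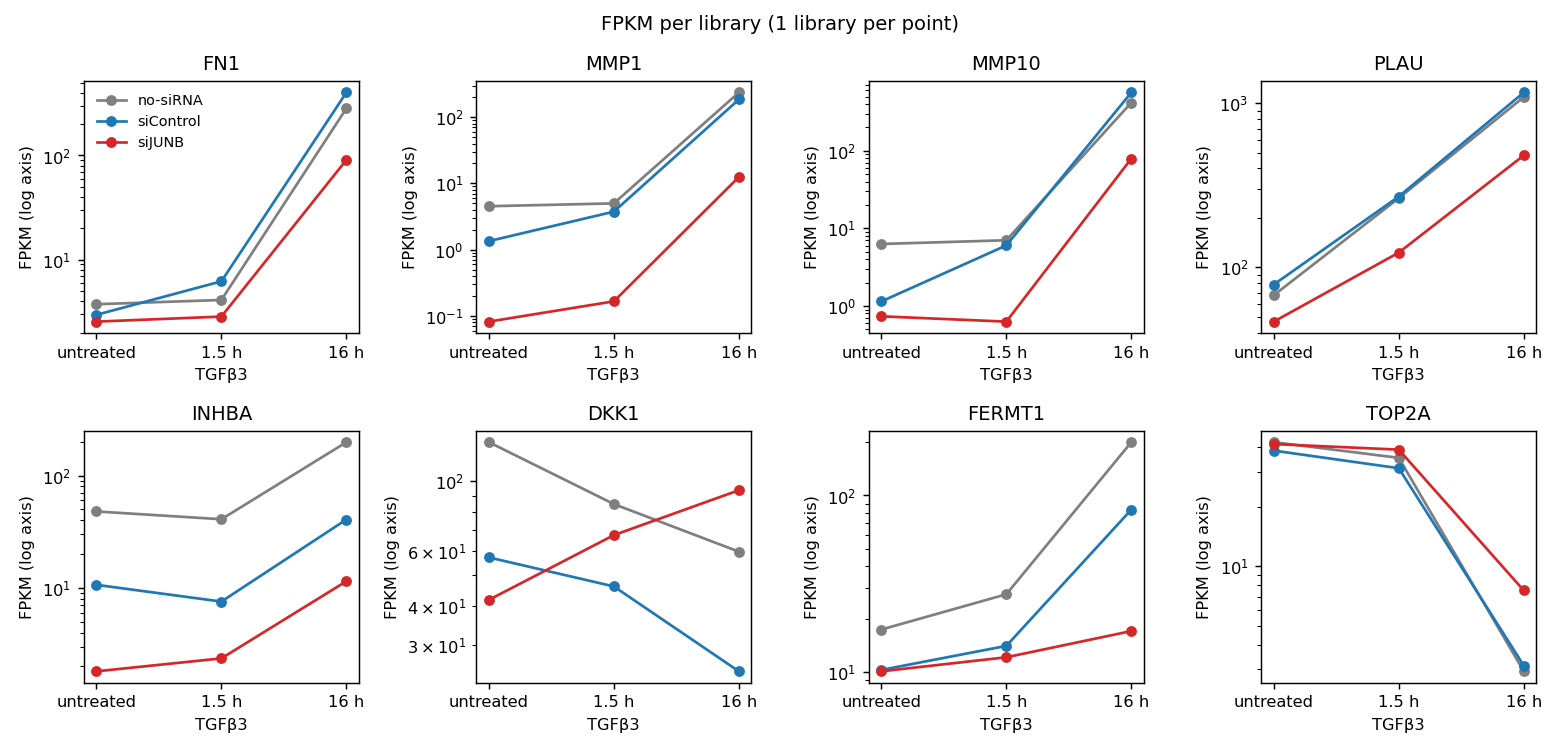
FPKM on a log axis of FN1, MMP1, MMP10, PLAU, INHBA, DKK1, FERMT1 and TOP2A, 1 point per library, by time of TGFβ3 and series. After 16 h FN1 stands at 90.6 FPKM in siJUNB cells against 402 in siControl cells, and DKK1 at 93.6 against 24.7 FPKM.

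To compare the responses without choosing genes on the measured libraries, genes were chosen on the no-siRNA series and measured in the other series. The 897 genes raised at least 2-fold after 16 h in no-siRNA cells had a median response of 1.17 in siControl and 0.82 in siJUNB cells. The median difference between these was -0.32 (quartiles -0.58 and -0.068), and 703 genes (78.4%) had a smaller response in siJUNB cells. Expression-matched random lists gave medians of -0.013 to 0.038 in 95% of draws, and none of 10000 was as low. These lists were drawn from all tested genes, not from genes that respond to TGFβ3. Any general weakening of the response in siJUNB cells would therefore put the panel outside their range. In the no-siRNA series, on which the panel was chosen, its median response was 1.34, above that of siControl too. The difference of levels between siJUNB and siControl was -0.063 in untreated cells and -0.40 after 16 h. For the 893 genes lowered at least 2-fold, chosen after the raised genes had been seen, the median response was -1.27 in siControl and -0.83 in siJUNB cells, a difference of 0.44. The 65 genes raised at 1.5 h had medians of 1.29 and 1.02, and a median difference of -0.078 (quartiles -0.33 and 0.12), below the range of 95% of random lists (-0.039 to 0.076). It was 0.012 with a pseudocount of 5 and -0.001 for genes raised at least 1.5-fold. These are descriptions of 6 libraries without a test.

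**Figure D5:**
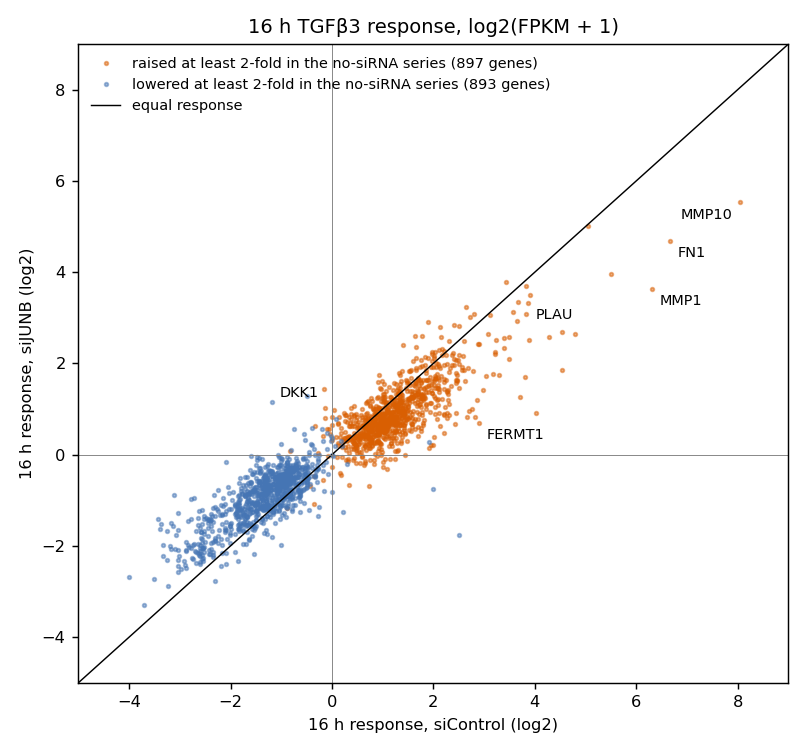
The 16 h response, log2(FPKM + 1), in siControl (x axis) and siJUNB cells (y axis), 1 point per gene, for the 897 genes raised and the 893 lowered at least 2-fold in the no-siRNA series. The line marks equal responses, and 78.4% of the raised genes lie below it.

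The siControl and no-siRNA series differed in the control siRNA and in the sequencing instrument (HiSeq 2500 and HiSeq 2000), so that these cannot be told apart. Whether the no-siRNA cells were mock-transfected is not given in the sources used here. SAA1, an acute-phase protein gene, was higher in siControl by 5.21 (SE 0.13, limma adjusted p = 2.3e-06), at 83.6 to 118 FPKM against 1.54 to 1.59. SAA2 (4.56), the iron-binding lipocalin gene LCN2 (4.42), complement C3 (3.98), PDZK1IP1 (3.90), the calprotectin subunit S100A9 (3.66), the interferon-induced IFITM1 (3.65), the matrix protein gene MGP (3.53) and CA9 (3.31) were higher as well. RPL21P28 (10.1) is a ribosomal pseudogene in a shared locus, and its value is uncertain. INHBA (-2.21), KRT6A (-2.17), AKAP12 (-2.67), the transcript ESRG (-2.62), FAM166A (-3.38), SRGAP2B (-2.22), RPPH1 (-2.38), the pseudogene HNRNPA1P10 (-3.41) and the mitochondrial-like genes MTRNR2L1 (-4.42) and MTRNR2L9 (-2.34) were lower. SAA2, INHBA, ESRG, FAM166A, SRGAP2B and HNRNPA1P10 also lie in loci shared by 2 to 4 genes, so that their values are less certain.

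In total 2635 genes were higher and 2220 lower in siControl than in no-siRNA cells. The excess of higher genes turned with rescaling, to 2374 higher and 2559 lower with median ratios and 2383 and 2601 with upper quartiles. Of 37 ribosomal protein genes 35 were higher (36 adjusted over the list alone), with a median of 0.99 and RPS13 at 1.54. Of the NF-kB and inflammatory genes 12 were higher and 2 lower (13 and 2 adjusted over the list alone), and of the glycolysis and hypoxia genes 11 and 1 (11 and 2 adjusted over the list alone), with CA9 and BNIP3 (1.58) highest. Of the basal genes 9 were lower and 0 higher (11 and 0 adjusted over the list alone), led by KRT6A and KRT14 (-1.41), of YAP/TEAD targets 9 and 0 (10 and 0 adjusted over the list alone), led by AMOTL2 (-1.21) and CYR61 (-1.07). Lower and higher members numbered, of matrix genes 12 and 4 (14 and 4 adjusted over the list alone), with LOXL4 (1.73) and LOX (1.66) furthest from 0, and of AP-1 genes 7 and 2, with FOSL2 (-0.88) and MAFK (-0.86) lowest and the same counts adjusted over the list alone. The differences went with transcript length (Spearman's rho -0.464 across 11430 genes), and with length and GC trends removed the calls over these genes went from 2507 higher and 2139 lower to 1797 and 2098, with 2869 genes in both. Without the filter on low values 1000 and 785 genes were called.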

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

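The tests of scaling, untreated level, mixture, length, instrument and other splits were chosen only after the result was seen, and those of small RNA genes before. The test of the response difference called 6 small RNA genes, higher in siJUNB than in both control series. At 1.5 h these were SCARNA16 (3.98, limma adjusted p = 0.0308), SNORA45A (9.77, limma adjusted p = 0.00106), SNORA61 (7.66, limma adjusted p = 0.0308) and SNORA66 (8.30, limma adjusted p = 0.00171), and at 16 h SNORA33 (8.32, limma adjusted p = 0.000253) and SNORA5C (9.68, limma adjusted p = 0.0201).

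Small RNA genes had residual SDs 8.08 times those of other genes of the same mean expression, which fits noise of very short genes as the source of these calls. Of 98 such genes 92.9% had a lower bound of 0 in at least 1 library, against 26.1% of other genes, and 78.6% were at 0 in at least 1 library, against 0.9%. At 1.5 h 41.8% of these genes had a difference above 0, so that no shift in 1 direction shared by most of them was seen. A change of small RNA content cannot be excluded by this, as most of these genes were at 0 in some library. Their share of the FPKM sum went from 3.21% to 9.80% at 1.5 h in no-siRNA, from 4.33% to 2.79% in siControl and from 4.52% to 6.54% in siJUNB cells. No biological explanation was tested.

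The 16 h response was smaller in siJUNB than in siControl cells in both the raised and the lowered panel. A scaling factor per library would shift both panels the same way, and is argued against by the difference of 0.437 in the lowered genes, opposite in sign to the raised genes. A raised untreated level is argued against in the raised genes by the untreated difference of -0.063, while in the lowered genes it was -0.105, the direction that lessens their fall, so that a part of the 0.437 stays open to it. A mixture with unstimulated RNA or cells cannot be told apart. The kept share of the change varied between raised genes no more than between the control series (ratio of interquartile ranges 0.838). A mixture would also keep equal median shares in both panels, and these were 57.5% in raised and 67.2% in lowered genes. Between the control series the medians were unequal too, at 73.9% and 86.3%, so that this cannot decide the question. The shares were taken over genes above a minimum FPKM change and changed in the same direction. The condition on direction left out 6 of 612 raised and 3 of 598 lowered genes in siJUNB, against 10 of 705 and 7 of 663 between the control series. An effect of JUNB on the response stays open beside a mixture.

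Ribosomal protein and inflammatory genes were higher in siControl than in no-siRNA cells. Length and GC content as the whole source are argued against. Before their removal the ribosomal median was 0.993 (95% of random lists from 0.211 to 0.771) and the inflammatory median 0.616 (random -0.222 to 0.223). After removal the medians were 0.575 (random -0.08 to 0.392) and 0.481 (random -0.219 to 0.136). With the longest transcript these were 0.645 and 0.391. The removal lowered the ribosomal genes called from 35 to 26 and the correlation with length from -0.464 to 0.016. The instrument cannot be told apart from the control siRNA, since both differ between these series; between siJUNB and siControl, which share it, the ribosomal median was -0.129.

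Splits of the 6 libraries other than the real 1 called at most 12 genes between siJUNB and siControl (real 259) and 0 between siControl and no-siRNA (real 4855, limma), so that 1 of 10 splits reached the real number in each comparison. With 10 splits a share under 0.05 is out of reach. The libraries are paired by time, and the 3 other splits that part each pair called 0, 2 and 0 genes between siJUNB and siControl, while the rest put both libraries of a time on the same side.

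Of 118 named genes, 27 changed at 1.5 h in siJUNB opposite to both control series, against 13 for siControl and 24 for no-siRNA as the odd series. At 16 h the numbers were 14, 7 and 10. Only 4 of the 27 and 2 of the 14 changed at least 1.5-fold in all 3 series. Some of these genes were chosen for a large difference in siJUNB. The differences were not tested for this. The 1.5 h responses in siJUNB were -0.0918 for MMP10, 0.0246 for FAM111B, 0.0266 for PTGES, -0.24 for SPC24, 0.0716 for GABRP, 0.22 for FOXI1, 0.24 for GRAMD2, -0.00675 for SMIM3, 0.26 for INHBA, 0.0866 for C10orf10, -0.00755 for ZBED2, -0.0239 for FOSL1 and 0.17 for BATF3. They were 0.67 for DKK1, 0.23 for RPL36A-HNRNPH2, 1.08 for NBEAP1, -2.77 for RPPH1, -2.74 for RMRP, -0.30 for CGB8, -0.26 for CGB7, -1.21 for IL10RB-AS1, -0.65 for HIST2H3D, -0.89 for HIST1H2AJ, 0.09 for RPL21P28, 0.16 for SAA1, -0.71 for IFITM1 and -0.27 for ESRG.

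The 16 h responses in siJUNB that went against both control series were 1.15 for DKK1 (-1.15 in no-siRNA, -1.18 in siControl), 1.29 for NRARP (-2.02 and -0.50), 1.66 for PI3 (-0.51 and -0.02), 0.15 for CEBPD, -0.61 for CXCL3, 0.52 for LOXL4, 0.69 for LOC102723505, -1.77 for IL10RB-AS1, -0.41 for IFITM1, 0.45 for CA9, -0.0723 for ESRG, 0.13 for FOSL1, 0.0381 for BATF3 and -0.0133 for JDP2. These differences were not tested as a set.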

How the results depend on the processing

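The tests without small RNA genes, of the lowered panel, of the rescaled JUNB level and with length and GC removed, or over the same genes before, were chosen only after the result was seen. No gene named for its large change in a tested comparison reversed in that comparison. Genes named only as members of AP-1 or another list did not enter this check. The JUNB level kept its direction under both rescalings. Of the list medians 1043 moved by at most 1 SD of the matched random lists, 229 by more and 2 reversed. The WNT list with JUNB siRNA was 0.009 without the filter (-0.169), and the stromal list between siControl and no-siRNA was 0.212 with an FPKM of at least 5 (-0.799). The cause was not tested for any change below, other than fewer libraries in the left-out times.

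At 1.5 h of TGFβ3 the genes higher (45) were 0 without the filter (534 at unadjusted p under 0.05 in limma), 75 with all 3 series as blocks, 69 without small RNA genes and 19 with length and GC removed (48 over the same genes before). Those lower (5) were 3 with a pseudocount of 5, 0 without the filter (327 at unadjusted p under 0.05 in limma), 3 without the trend, 12 with all 3 series and 14 without small RNA genes. Without the filter the calls were 1270 and 1225 at 16 h, 831 and 965 between the times, and 1000 and 785 between siControl and no-siRNA.

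With JUNB siRNA, 50 genes higher and 209 lower became 5 and 27 with a pseudocount of 0.1, 26 and 104 with 5, 9 and 35 with median-ratio and 14 and 28 with upper-quartile rescaling. They became 0 and 0 in limma without the filter (1300 and 1946 at unadjusted p under 0.05) and 0 and 0 without the trend (1141 and 1748 at unadjusted p under 0.05). Leaving out 1 time gave 0 to 2 higher and 0 to 17 lower in limma (at unadjusted p under 0.05, 1142 lower without the untreated pair, and 558 higher and 1086 lower without the 1.5 h pair). Lower were 324 with an FPKM of at least 5. Without small RNA genes 159 and 563 were called, against no-siRNA, where the instrument differs, 2489 and 2226, and with length and GC removed 80 were higher (48 over the same genes before). The rescaled calls were among the 259 in 44 of 44 and 42 of 42 genes.

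The response difference at 1.5 h (4 higher, 0 lower) had 2 higher and 1 lower without the filter, 0 higher without small RNA genes (40 at unadjusted p under 0.05 in limma), 1 higher with length and GC removed (3 over the same genes before) and 1 lower with a pseudocount of 5. At 16 h (2 higher, 0 lower) it had 1 higher without the filter, against siControl alone, without small RNA genes and with length and GC removed (2 over the same genes before). Lower were 1 with a pseudocount of 0.1, 3 with 5, 1 without the filter, 1 with an FPKM of at least 5 and 1 without small RNA genes.

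The panel raised at 1.5 h (-0.078) was -0.024 with a pseudocount of 0.1, 0.012 with 5, -0.041 with an FPKM of at least 5, -0.001 at 1.5-fold and -0.117 with length and GC removed (-0.086 over genes with these values). The panel raised at 16 h (-0.324) was -0.301 with an FPKM of at least 5, -0.307 with median-ratio rescaling, -0.21 at 1.5-fold, -0.506 at 3-fold and -0.356 with length and GC removed (-0.336 over genes with these values). The lowered panel (0.437) was 0.478 with a pseudocount of 0.1, 0.378 with 5, 0.46 with an FPKM of at least 5, 0.41 with upper-quartile rescaling, 0.309 at 1.5-fold and 0.502 at 3-fold. Depth is unknown and limits weakly expressed genes most.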

Other observations

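The tests of protease and cell cycle genes were chosen only after the result was seen, and that of late genes before. Of the 897 genes raised at 16 h in no-siRNA cells, the 750 that were not raised 1.5-fold at 1.5 h had a median difference of the 16 h response between siJUNB and siControl of -0.339, and the 147 that were had -0.249. The difference of -0.09 lay below 95% of random divisions (-0.08 to 0.082, percentile 1.18) and of divisions matched on the no-siRNA response (-0.01 to 0.151). This is the direction predicted if late genes depend more on JUNB. The divisions shuffle genes and do not measure the spread between libraries, so that dependence on JUNB is not shown by them. The same libraries would show such a difference if the responses differed for another reason, and 1 siRNA pool was used.

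The 13 proteases of the raised panel had a median difference of -0.533, inside the range of raised genes matched on the no-siRNA response (-0.99 to -0.235, percentile 62.19). A larger loss of the 16 h response than in other genes raised as strongly was not found for proteases. The 27 cell cycle genes of the lowered panel had a median of 0.498, inside the range of matched lowered genes (0.49 to 0.875, percentile 4.67), and a larger loss than in other lowered genes was not found for them either.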
